A study of Drosophila melanogaster with 8 samples.

How the data were processed

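The deposited table held 1 value per spot for each of 8 arrays, 4 of heads collected on day 10 and 4 of heads collected on day 14. Each array carried labelled RNA of treated flies and of control flies kept in parallel. The series text describes sets of paired control and treated pools, but whether any control RNA was shared between arrays could not be checked. Per the labels' protocols and the series text, slides were scanned on a GenePix scanner, quantified with GenePix Pro 6.0 and ratio-normalised by the authors with Acuity 4.0. Per the same text, the authors ignored spots below 100 intensity units during normalisation and then kept only spots that passed filters. Those left out had 3 percent or more saturated pixels, with an R2 between the channels under 0.6 or with a signal-to-noise ratio under 3. Blank cells were therefore taken as filtered spots. The deposited values were log2 ratios, judged from the values: they were signed, lay near 0, and 2 of them equalled 16.6, the log2 of a ratio capped at 100000. Those 2 were left out. No column of other samples was present.

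The medians of the 4 day 10 arrays were -0.27, -0.32, 0.00 and -0.25, and those of the day 14 arrays -0.34, -0.11, -0.06 and -0.06, so arrays were not centred at deposit, and each was centred on its median here. The direction of the deposited ratio was not stated. Adjacent rows were duplicate spots of one clone (correlation 0.46 to 0.79 on an array). The table was taken to run through 48 print blocks of 576 rows, and the medians of these blocks carried a pattern over the slide. Block medians of named spots on one array and of unnamed spots on another of opposite dye orientation correlated at 0.18 to 0.83, above 0 in all 16 such pairs. Since a pattern of the slide and scanner keeps its sign in Cy5 over Cy3 whatever RNA carries the dye, the swapped arrays were taken as not yet turned, and their sign was turned before the fit. Which channel stood on top of the ratio was taken from the labels (Cy5 in channel 1) and from scanner convention.

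Gene names came from the platform annotation and were updated through gene IDs to the RefSeq table of assembly Release 6 plus ISO1 MT. Of the 27648 rows, 15116 named 1 gene, 102 several and 12430 none, and 14894 of the first matched the RefSeq table. No coordinates are given, since the array's genome build was not given in the sources used here. Rows of the same single gene were averaged (6793 genes), and rows without a single gene name were tested on their own. Rdl, HDAC1, HDAC3 and para, which were to be given where measured, were not among the named rows and are not analysed here.

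Tests were made with limma 3.58.1 in R 4.3.3 on the log2 scale. All 8 arrays entered one fit with a mean for each group and a gene-wise dye term. A gene needed values on at least 3 of the 4 arrays of each group compared. Moderated p values were adjusted by the Benjamini-Hochberg method over all features tested, with 0.05 as the threshold. For genes with missing values the fit was solved exactly for each pattern of missing arrays, and on genes with all values its p values were checked against limma's own. On simulated arrays with the real missing values, a log2 change of 1 in 200 genes was recovered for 91.0% of them at day 10 (11509 features), 91.5% at day 14 (7529 features) and 79.0% in the difference (6419 features). A change of 0.5 was recovered for 13.5%, 12.0% and 0%. The simulated noise was independent between features and scaled to the median residual SD of each group (0.26 and 0.19). It held no slide pattern, though print blocks carried up to 33.7% of the variance on a real array. The changed genes all had values on at least 3 arrays of both groups. The shares recovered can therefore be too high for the real arrays. In these simulations 2.24% of unchanged features at day 14 had an unadjusted p under 0.05 in the joint fit and 4.64% with the group fitted alone; at day 10 the joint fit gave 6.72%.

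Gene lists were 31 sets of pathway genes and cell type markers. They were tested with cameraPR at a preset correlation of 0.01 where at least 5 members were measured, adjusted over the lists, and again with camera and an estimated correlation on the 3543 features with values on all arrays. Of the 31 lists, 30 were tested at day 10, 27 at day 14 and 26 in the difference; the male reproductive tract list was too small in each. After the data were examined, the cyclophilin gene Cyp40, which shares a name prefix with P450 genes, ribosomal-protein-like genes and a mismatched synonym in the male tract list were taken out of the lists. The estimated correlation used fewer genes per list, 12 for P450 genes.

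Apart from those corrections to the lists, the lists, groups, tests and the rule for named genes were fixed before the data were examined. The rule named, in each comparison, up to 12 genes per direction past the threshold with all arrays the same way. Where fewer than 10 passed it named the 10 with the smallest p, and for each list up to 4 members past the threshold or else the 2 with the smallest p. It always named Rdl, Gad1, HDAC1, HDAC3, HDAC6 and para where measured, and at most 2 rows without a gene name per direction, of which none is named here. HDAC6 had a value in the test at day 10 and not at day 14. Other settings fixed at the same time were no centring, scaling to one spread, other limits on missing values, no dye term, each group fitted alone, rows not averaged, swapped arrays read as already turned, other variance moderation, each array left out, a threshold of 0.1, the replicate number as a block and an estimated correlation. Added after the data were examined were print-block centring, a dye term for each group, the capped values kept, unnamed rows averaged in pairs and lists with every prefix match. Slide and scan dates were not given in the sources used here.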

Results

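Head RNA of unmated male Drosophila melanogaster of the wild-type strain Oregon-R was compared with head RNA of parallel control flies on 2-colour cDNA arrays. Flies aged 3 to 4 days ate food with pentylenetetrazole for 7 days and then food with sodium valproate for 3 days. Pentylenetetrazole blocks GABA-A receptors and causes seizures, and valproate is an antiepileptic drug that also inhibits histone deacetylases. One group was collected on day 10, at the end of valproate (n = 4 arrays). The other was moved back to normal food for 4 further days and collected on day 14 (n = 4 arrays). Each array set treated RNA against RNA of control flies kept on normal food for the same time, and 2 of the 4 arrays in each group had the dyes swapped. The series text calls the 4 arrays of a group biological replicates. The sample labels give 8 mg/ml pentylenetetrazole and 0.33 mg/ml valproate, while the series text gives 0.33 and 24 mg/ml, so the doses are not settled here.

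The arrays carried 27648 spots, of which 13524 to 19905 had a value on the day 10 arrays and 11208 to 14421 on the day 14 arrays. The SD of the log2 ratios over an array was 0.52 to 0.86 at day 10 and 0.33 to 0.43 at day 14, and the number of arrays limits the precision. Ratios below are log2 values of treated over control RNA, with the error as the standard error of the limma fit and n as the number of arrays. The relative direction of the arrays was settled from the data, but the overall sign rests on the reading that each deposited value is Cy5 over Cy3. That reading is likely, since the labels put Cy5 in the first channel of every array, but it was not stated. With the opposite reading every higher value below would be a lower one. In the plot of print-block medians, the pattern over the slide ran the same way on arrays of opposite orientation, so swapped arrays had not been turned before deposit.

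**Figure D1:**
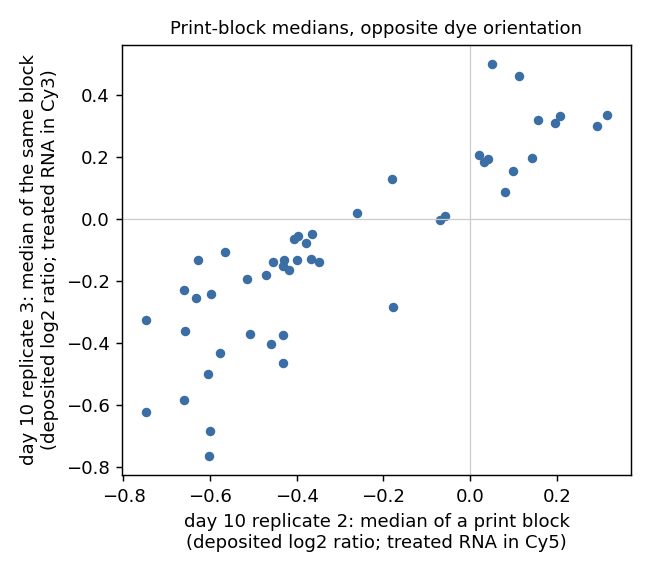
Each point is 1 of 48 print blocks; the axes give the median deposited log2 ratio of the block on day 10 replicate 2 (treated RNA in Cy5) and on day 10 replicate 3 (treated RNA in Cy3). The medians rise together (r = 0.865), although the treated RNA carried opposite dyes. This is the strongest of the 16 pairs of opposite orientation, which ranged from 0.179 to 0.865.

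The day 10 comparison asked how head RNA stood at the end of valproate feeding after pentylenetetrazole. The cytochrome P450 genes, enzymes that oxidise drugs, toxins, lipids and hormones, fell as a group: 34 of 48 measured members lay below 0, with a median log2 ratio of -0.16 (adjusted p = 0.0015 with limma's cameraPR). That call was lost at adjusted p = 0.46 with an estimated correlation, on the 12 P450 genes with values on all 8 arrays. No single member passed, over all genes or adjusted over the list alone (0 genes each), and 6 lower members and 1 higher one had an unadjusted p under 0.05. Cyp313a1 was at -0.60 ± 0.14 (n = 4, 1.51-fold lower) and below 0 on all 4 arrays, and Cyp6d4 was at -0.75 ± 0.21 (n = 3). The list also lost its call without day 10 replicate 1 (adjusted p = 0.062) or without day 10 replicate 3 (0.16). A gene then needed values on all 3 remaining arrays of the day, which left 28 and 43 of the 48 P450 genes. These losses therefore mix a missing array with a shorter list.

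Among 11509 features tested at day 10, 5232 named genes and 6277 spots without a gene name, limma called 0 at an adjusted p of 0.05, with 768 at an unadjusted p under 0.05 (430 higher, 338 lower). An even spread of p values would give 575. The 768 were 6.67% of features, against 6.72% of unchanged features in the simulation, which held no slide pattern. The 10 named genes with the smallest p are given as values that did not pass (adjusted p = 0.70 for gt and 0.73 for the others). The gap transcription factor gene gt was at -1.94 ± 0.19 (n = 3), with an SD of 1.40 between its arrays. CG5768 was at -1.24 ± 0.23 (n = 3), CG10958 at -0.93 ± 0.17 (n = 3) and CG9427 at -0.85 ± 0.16 (n = 3). The SDs between their arrays before the dye term were 0.94, 0.54 and 0.35, a spread that the standard error after the dye term can understate. The endosomal phosphatase-like gene mop stood at -0.77 ± 0.16 (n = 3) and salt at -0.74 ± 0.16 (n = 3). Higher values belonged to CG4953 at 0.84 ± 0.18 (n = 4), the cuticle protein gene Cpr65Ax2 at 0.74 ± 0.16 (n = 3) and the autophagy protease gene Atg4a at 0.58 ± 0.12 (n = 4). Atg4a and CG4953 were above 0 on all 4 arrays, and Cyp313a1 completes the 10.

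None of the other 29 lists passed at day 10 (adjusted p from 0.79 to 0.997), and 0 of their genes were called, over all genes or adjusted over the list alone. The 2 members of each list with the smallest p follow as values, each on 3 or 4 arrays. For the targets of the drugs, GABA signalling had GABA-B-R3 at 0.28 ± 0.19 and Gabat at -0.18 ± 0.15, and the GABA-synthesising enzyme gene Gad1 was at 0.14 ± 0.14. Histone acetylation genes included chm at 0.41 ± 0.20 and Sirt7 at 0.27 ± 0.15, and the deacetylase gene HDAC6 was at -0.12 ± 0.21. Voltage-gated and related channel genes included ClC-b at -0.47 ± 0.17 and Irk2 at -0.36 ± 0.14. Transmitter receptor genes included the nicotinic subunits nAChRalpha4 at 0.46 ± 0.15 and nAChRbeta3 at 0.40 ± 0.17. In the synaptic vesicle list EndoA was at -0.47 ± 0.23 and Clc at 0.18 ± 0.12. Pdf, a neuropeptide of clock neurons that stood in the neuropeptide and the circadian lists, was at 0.45 ± 0.15 and above 0 on all 4 arrays. Eh was at -0.69 ± 0.20 and the clock gene Pdp1 at -0.50 ± 0.37. Learning genes gave S6kII at 0.51 ± 0.31 and Pka-R1 at 0.29 ± 0.18, and the inositol list IP3K2 at 0.21 ± 0.14 and Axn at 0.33 ± 0.23. In the list of cytoskeleton and axonal transport, Mlc-c was at 0.35 ± 0.13 and cpa at 0.28 ± 0.21.

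In the metabolic lists of day 10, glycolysis and TCA cycle genes had Pgk at 0.23 ± 0.13 and SdhB at 0.27 ± 0.15, and respiratory chain genes ND-20 at 0.40 ± 0.17 and COX4 at 0.41 ± 0.18. Lipid genes included mdy at -0.88 ± 0.21 and AcCoAS at 0.24 ± 0.12, and the transferases Ugt37E1 at -0.75 ± 0.31 and GstO1 at -0.93 ± 0.46. Antioxidant genes had Keap1 at 0.53 ± 0.17 and Sesn at 0.27 ± 0.14, and chaperones CCT8 at 0.56 ± 0.17 and Fkbp14 at -0.35 ± 0.15. Protein turnover was represented by the proteasome genes Rpn5 at 0.47 ± 0.15 and Rpn2 at 0.56 ± 0.24, the ribosomal genes RpS5b at -0.26 ± 0.16 and RpL39 at 0.19 ± 0.12, and the mitochondrial ribosomal genes mRpS11 at -0.29 ± 0.14 and mRpS29 at 0.26 ± 0.13. Immune genes included the antifungal peptide gene Drs at -0.46 ± 0.18 and spz at -0.29 ± 0.17, and digestive enzymes Amyrel at 0.36 ± 0.14 and LManII at -0.32 ± 0.16.

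Among markers of cell types at day 10, neuronal genes had Nrt at 0.42 ± 0.17 and nSyb at 0.24 ± 0.17, glial genes Mdr65 at -0.76 ± 0.26 and e at -0.39 ± 0.21, and photoreceptor genes Cpn at 0.38 ± 0.24 and Slob at 0.25 ± 0.17. Fat body markers had Cyp4d21 at -0.54 ± 0.20 and Fbp2 at 0.45 ± 0.20, with a list median of -0.05. Muscle genes included flr at -0.69 ± 0.19 and Act87E at -0.17 ± 0.13, and haemocyte genes eater at 0.48 ± 0.23 and PPO3 at 0.24 ± 0.15. Cuticle genes included Cpr72Ea at 0.62 ± 0.18 beside Cpr65Ax2, and the chemosensory list Obp99a at -0.51 ± 0.20 and Obp56e at 0.27 ± 0.16. Median and mean differed in sign for the channel, transferase, cytoplasmic ribosomal and lipid lists. For 16 of the genes named at day 10, at most 2 of 4 arrays or 1 of 3 had the sign of the fitted value, and the SD between arrays was 0.37 to 1.18, so the standard error after the dye term understates how far the arrays spread. CCT8 (2 of 4, SD 1.18), cpa, EndoA, COX4, Nrt, nSyb, PPO3, Sirt7, SdhB, Irk2, Gabat and Gad1 were split by dye orientation. So were Cpr72Ea (1 of 3, SD 0.97) and Rpn2 (1 of 3, SD 1.02), while S6kII and Axn were split in another way.

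The day 14 comparison asked how head RNA stood after the flies had returned to normal food. Of 27 lists tested, 5 fell under the preset correlation, and 0 of 20 passed with an estimated correlation on genes with values on all 8 arrays. The estimates were 0.0053 for glycolysis and 0.016 for P450 genes, near the preset 0.01. At the preset on those same genes both lists passed (adjusted p = 0.0066 and 0.0017 with camera). Fat body markers had an estimate of 0.30 and did not pass there (adjusted p = 0.17). Glycolysis and TCA cycle genes had a median log2 ratio of -0.24, with 13 of 15 below 0 (adjusted p = 0.0029, and adjusted p = 0.18 with an estimated correlation). Cytochrome P450 genes had a median of -0.13, with 23 of 36 below 0 (adjusted p = 0.0029, and 0.18 with the estimate). Fat body markers had a median of -0.17, with 7 of 9 below 0 (adjusted p = 0.0077, and 0.57 with the estimate), but the list's median on day 14 replicate 2 was above 0, at 0.18. Glial markers stood at -0.17, with 7 of 9 below 0 (adjusted p = 0.046, and 0.57 with the estimate). Genes of fatty acid oxidation and lipid metabolism stood at -0.08, with 11 of 12 below 0 (adjusted p = 0.047, and 0.26 with the estimate).

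With the estimate, 3 of the 20 lists, those of glycolysis, P450 and lipid genes, had an unadjusted p under 0.05. Leaving out 1 array ended the call of glycolysis (adjusted p = 0.075 without day 14 replicate 1 and 0.051 without day 14 replicate 4), of P450 genes (0.051 without day 14 replicate 4) and of fat body markers (0.062 without day 14 replicate 2). The glial list lost it without any 1 of the 4 day 14 arrays or without day 10 replicate 2 (0.051 to 0.51). The lipid list lost it without any 1 array except day 10 replicate 3 (0.052 to 0.18). Leaving out a day 14 array could also shorten a list, such as the lipid list from 12 genes to 8 without day 14 replicate 1.

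The glycolysis list was led by Gpdh1, which links glycolysis to glycerol lipids and lay at -0.55 ± 0.14 (n = 4). Tpi followed at -0.25 ± 0.12 (n = 4). Of single members, 0 were called over all genes and 1, Gpdh1, adjusted over the list alone. Among P450 genes, Cyp313a1 was at -0.82 ± 0.13 (n = 4, 1.77-fold lower) and Cyp4d21, also called sxe1, at -0.77 ± 0.18 (n = 4, 1.70-fold lower). Of this list 0 genes were called over all genes and 5 adjusted over the list alone, which also included Cyp9f2, Cyp4e2 and Cyp28d1. The fat body list was led by sxe2, a lipase-like gene, at -0.67 ± 0.13 (n = 4) and by Cyp4d21. Those 2 were its calls adjusted over the list alone, with 0 over all genes. Cyp4d21 counted in the P450 and the fat body list, and FASN1 in the lipid and the fat body list. The glial list was led by alrm at -0.51 ± 0.19 (n = 3) and Gs2 at -0.23 ± 0.13 (n = 4). The lipid list was led by AcCoAS at -0.35 ± 0.12 and yip2 at -0.26 ± 0.13 (n = 4 each). Of the glial and lipid lists 0 genes were called, over all genes or adjusted over the list alone.

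**Figure D2:**
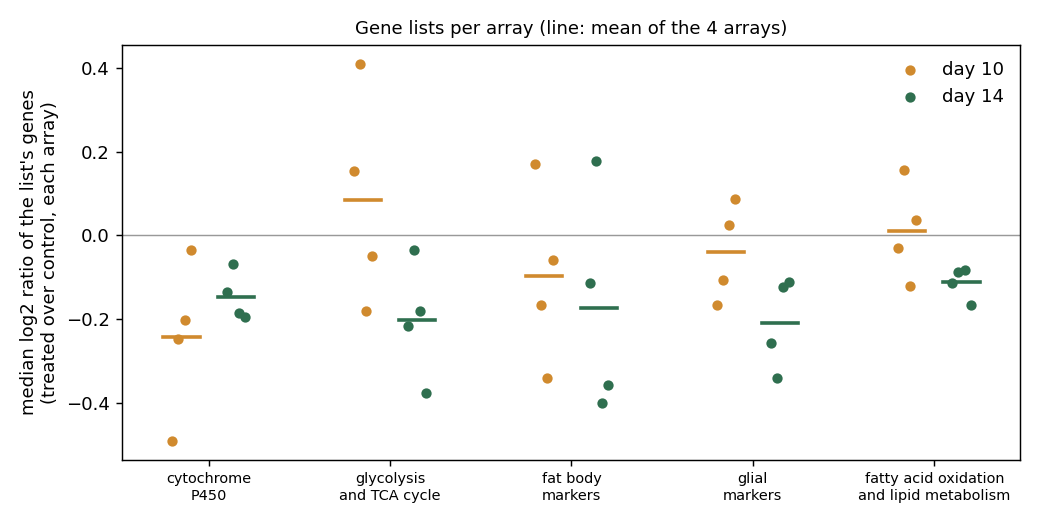
Points give the median log2 ratio (treated over control) of the genes of each list on each array, day 10 in orange and day 14 in green, and lines the mean of the 4 arrays of a group. The P450 medians lie below 0 on all 8 arrays, from -0.49 to -0.04, while the fat body medians at day 14 run from -0.40 to 0.18.

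Among 7529 features tested at day 14, 3172 of them named genes, limma called 0 in the fit of both groups together, with 300 at an unadjusted p under 0.05 (107 higher, 193 lower). An even spread of p values would give 376. The 300 were 3.98% of features, against 2.24% of unchanged features in the simulation, so they do not compare directly with the count at day 10. Each group fitted alone had 887 such features at day 14 and 583 of 11509 at day 10. The day 14 arrays fitted alone gave 70 calls (18 higher, 52 lower), of which 27 were named genes. The other 43 were rows without a single gene name, where duplicate spots of 1 clone can count more than once. Scaling the arrays to one spread gave 39 calls (4 higher, 35 lower), of which 38 were also among the 70. The 10 named genes with the smallest p in the joint fit had adjusted p values of 0.44 to 0.75 there, and all 10 passed in both of those other fits. Beside Cyp313a1, Cyp4d21, sxe2 and Gpdh1 they were CG7966 at -0.67 ± 0.12, CG4914 at -0.57 ± 0.12, CG9689 at -0.69 ± 0.15 and Cyp9f2 at -0.78 ± 0.19 (n = 4 each). CG9689 lay below 0 on only 3 of its 4 arrays, with an SD of 0.55. The blue-light receptor gene cry, part of the circadian clock, was at -0.58 ± 0.14 (n = 4) and below 0 on all 4 arrays. CG31183 was at 0.93 ± 0.18 on 3 arrays, only 1 of which lay above 0 before the dye term, with an SD of 1.31. In the fit of day 14 alone, the other named genes among the 70 included Cyp28d1 at -0.57, Iris at -0.58 and crc at -0.50 (n = 4 each). Surf6 at -1.04, Cyp4e2 at -0.64 and CG18004 at 1.01 rested on 3 arrays, and those of CG18004 did not all lie the same way. Of the 70 calls, 56 had all arrays the same way. Without 1 of the 4 arrays, which leaves 1 residual degree of freedom, the day 14 arrays alone gave 24 to 386 calls, 24 without replicate 3 and 386 without replicate 2.

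**Figure D3:**
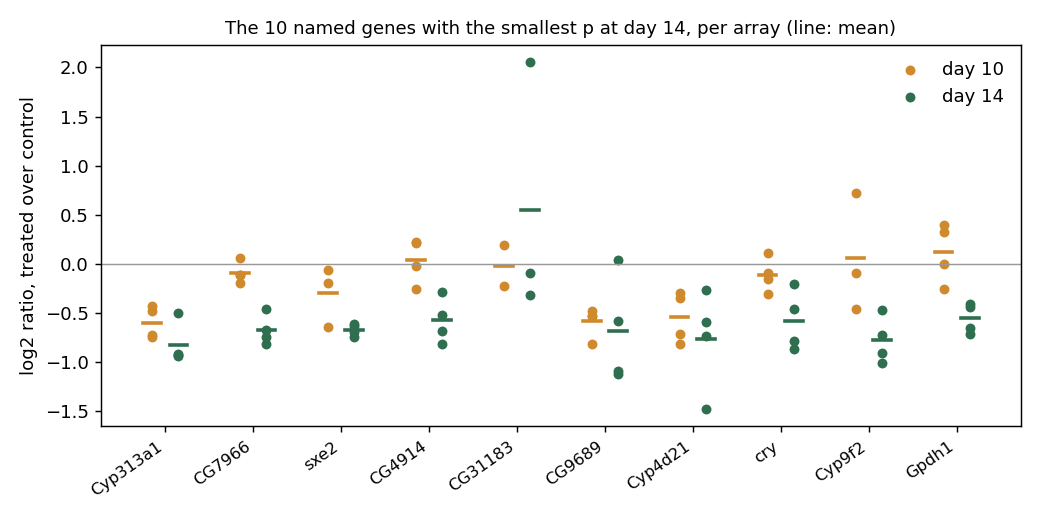
Points give the log2 ratio (treated over control) on each array for the 10 named genes with the smallest p at day 14, day 10 in orange and day 14 in green, and lines the mean. The 4 day 14 values of sxe2 lie close together around -0.67 (SD 0.06), while those of CG31183 spread widely.

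The other 22 lists did not pass at day 14 (adjusted p from 0.055 to 0.98), with 0 of their genes called over all genes and 1, cry, adjusted over the list alone. Cytoplasmic ribosomal genes came closest (adjusted p = 0.055), with a median of -0.12 and with RpL23 at -0.30 ± 0.14 and RpS7 at -0.32 ± 0.17. GABA signalling, with Gad1 at 0.03 ± 0.14, had fewer than 5 measured genes and was not tested. Histone acetylation genes included Smr at 0.18 ± 0.13 and MTA1-like at 0.18 ± 0.15, and channel genes Ca-beta at 0.37 ± 0.16 and stj at 0.27 ± 0.13. Serotonin receptors led the transmitter list, 5-HT2A at 0.29 ± 0.16 and 5-HT1A at 0.22 ± 0.12. Vesicle genes had unc-13 at 0.24 ± 0.14 and Rop at -0.24 ± 0.15, and neuropeptide genes Pdfr at 0.26 ± 0.13 and Capa at 0.21 ± 0.16. Pdp1 stood at 0.54 ± 0.28 beside cry in the circadian list. Learning genes gave Pka-R1 at -0.13 ± 0.17 and 14-3-3zeta at -0.09 ± 0.13, the inositol list Ipk2 at -0.15 ± 0.15 and sl at 0.11 ± 0.14, and axonal transport Klc at 0.21 ± 0.14 and Ank at -0.21 ± 0.16.

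Of the remaining lists at day 14, transferases had GstE12 at -0.33 ± 0.15 and GstD9 at -0.41 ± 0.20, respiratory chain genes levy at -0.21 ± 0.13 and ND-15 at -0.21 ± 0.13, and antioxidant genes Prx3 at -0.30 ± 0.18 and Gtpx at -0.24 ± 0.20. Chaperones had Hsc70-5 at -0.34 ± 0.16 and Fkbp14 at -0.26 ± 0.14, proteasome genes Rpt3 at -0.27 ± 0.15 and Prosbeta7 at -0.23 ± 0.15, and mitochondrial ribosomal genes mRpL37 at -0.40 ± 0.18 and mRpL33 at -0.27 ± 0.18. Immune genes included nec at -0.17 ± 0.15 and Drs at -0.15 ± 0.15, and digestive enzymes Jon66Cii at -0.28 ± 0.15 and Jon25Biii at 0.38 ± 0.26. Cuticle genes had Cpr65Ax2 at 0.31 ± 0.15 and Cpr67B at -0.41 ± 0.21, and chemosensory genes Obp99c at -0.30 ± 0.14 and Obp44a at -0.23 ± 0.14. Photoreceptor genes included Slob at 0.33 ± 0.16 and rdgA at 0.33 ± 0.17, and muscle genes Act79B at -0.21 ± 0.13 and Act88F at -0.24 ± 0.17. Median and mean differed in sign for the proteasome, mitochondrial ribosomal and inositol lists. Each of these values rests on 3 or 4 arrays, and for Rpt3, Act79B, 5-HT1A, Pka-R1 and 14-3-3zeta only 2 of 4 had the sign of the fitted value.

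The comparison of day 14 with day 10 asked whether the response differed after the return to normal food. Glycolysis and TCA cycle genes came closest among 26 lists, with 12 of 13 lower at day 14 and a median difference of -0.31, but did not pass (adjusted p = 0.055, and adjusted p = 0.50 with an estimated correlation). P450 genes passed at each day at the preset correlation and not with the estimate (adjusted p = 0.46 and 0.18). They had a median difference of 0.06 and a mean difference of -0.02 over 29 genes (adjusted p = 0.99). No list passed, and 0 genes of the lists were called over all genes. Adjusted over the list alone, 2 lipid genes were called, 1 lower and 1 higher at day 14. The glycolysis difference passed under some of the other settings, for example with all arrays scaled to one spread (adjusted p = 0.0049) or without day 10 replicate 1 (0.0042) or day 10 replicate 3 (0.014). The respiratory chain list passed without day 10 replicate 3 (adjusted p = 0.014), and the lipid list without day 10 replicate 1 (0.022).

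Among 6419 features tested for the difference, limma called 0, with 402 at an unadjusted p under 0.05 (158 higher, 244 lower at day 14). An even spread of p values would give 321. The 402 were 6.26% of features, against 4.74% of unchanged features in the simulation. The 10 named genes with the smallest p did not pass (adjusted p = 0.77 for each). Lower at day 14 than at day 10 were Stt3B, a subunit of the enzyme that glycosylates proteins, by a log2 difference of -1.14 ± 0.26 (n = 6), CG10283 at -1.10 ± 0.31 (n = 7) and CG6409 at -0.88 ± 0.22 (n = 8). CG7800 differed by -0.84 ± 0.23 (n = 7), CG2217 by -0.81 ± 0.20 (n = 8), Cyp4e2 by -0.78 ± 0.21 (n = 7) and CG4914 by -0.61 ± 0.18 (n = 8). Values higher at day 14 were those of salt at 0.85 ± 0.23 (n = 6), CG9427 at 0.81 ± 0.22 (n = 6) and the wing transcription factor gene vg at 0.73 ± 0.20 (n = 7). Across these 6419 features the ratios of the 2 days had a Pearson correlation of -0.02 and a Spearman correlation of -0.04, a description across genes, which are not independent replicates. Among the 2711 named genes alone these were 0.02 and -0.01. At an unadjusted p under 0.05, 154 of these named genes stood out at day 10, 106 at day 14 and 8 at both, where independent lists would share 6.02. As both days share a gene-wise variance in the fit, the lists are not independent and can share more without a common response.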

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

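All tests of explanations in this part were chosen after the result was seen, except the regroupings of arrays in its last paragraph. Of 176 sets of 4 values looked at (named genes, lists and array summaries), 9 had 1 array far from the other 3, and chance would give 8.8. On day 10 replicate 3, 13524 spots had a value, against 18976 to 19905 on the other arrays of that day. On day 14 replicate 4 duplicate spots correlated at 0.46, against 0.66 to 0.68. At day 10, CG9689 was at -0.81 on replicate 1 against -0.53 to -0.48, CG6409 at 0.70 on replicate 3 against 0.14 to 0.22, and levy at -0.23 on replicate 3 against 0.17 to 0.24. At day 14, Cyp313a1 was at -0.50 on replicate 4 against -0.94 to -0.91, and Pdf at -0.30 on replicate 1 against 0.24 to 0.34. Hsc70-5 was at -0.62 on replicate 3 against -0.27 to -0.24, and unc-13 at 0.78 on replicate 1 against -0.01 to 0.11.

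Read as already turned, the swapped arrays gave 304 calls at day 10 (264 higher, 40 lower). That reading needs block medians that run in opposite ways on arrays of opposite orientation, and 0 of 16 such pairs correlated below 0. Print-block centring ended all 304 calls (0 left): the median log2 ratio of these features in the called direction went from 0.84 to 0.55 with a standard error of 0.14 before and after, and 294 kept an unadjusted p under 0.05. Over all 11509 features, those at an unadjusted p under 0.05 went only from 3293 to 3008, and the smallest adjusted p from 0.044 to 0.11. The calls ended because the ratios shrank, so position on the slide carried part of them. These features were picked for large values before centring, so the shrinkage can overstate that part. Whether finer position carried the rest stays open. If the swapped arrays were not turned, as taken here, a treatment effect has opposite signs on swapped and unswapped arrays. It then cancels in the unturned mean of a gene with values on all arrays of the day. For such genes the design argues against a treatment response as the source of these calls. Effects of dye or slide keep their sign and do not cancel. A dye bias of single genes may be a source, since the unturned means of the 2 days correlated at 0.17 across genes after print-block centring. For genes that lack an array the cancelling is not exact, and a biological explanation was not tested.

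The day 14 arrays fitted alone called 70 features. A fit of both groups with a dye term of each group had the same estimates for all 7529 features and called 0, so only the pooled variance and its degrees of freedom differed (median standard error 0.12 alone and 0.14 pooled). The median residual SD was 0.26 at day 10 and 0.19 at day 14, and with the day 10 arrays divided by that ratio (1.40) 22 of the 70 calls came back, so the wider spread of day 10 carried part of the difference and the rest stays open. With the sign of single day 14 arrays turned, 7 patterns could be fitted, too few for a share under 0.05; the real pattern gave 70 calls, as many as 1 of the 7, and the highest other gave 7. An effect of the treatment at day 14 stays open and was not tested further.

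Of 27 lists, 5 fell at day 14 under the preset correlation and 0 with an estimated one (adjusted p from 0.18 to 0.57). Differences between print blocks were argued against as the whole source for the P450, glycolysis and fat body lists. These kept adjusted p values of at most 0.0038 with cameraPR after print-block centring. Centring cannot remove position within a block, so finer position stays open for them. Position on the slide of either kind stays open for glial markers (adjusted p = 0.099, mean -0.16 before and -0.12 after, with errors over list members, not arrays, of 0.06 and 0.05). It also stays open for lipid genes (0.081, mean -0.12 before and after, with errors over members of 0.03 and 0.04). The calls of these 2 lists had been near the threshold (0.046 and 0.047) and ended. A smaller share of fat body stays open. In the full list 7 of 9 members were below 0, and those above 0 were yolk protein genes, products of the female fat body. These were left out here, which made all 7 remaining markers lie below 0. Their median was -0.18, with an error of 0.14 over the markers, not over arrays. Of them, 2 were below 0 by over 2 of their own limma standard errors. Signal shared between P450 genes stays open, since the residuals of the 12 P450 genes with all values correlated at 0.016, near the median of 10000 random lists (0.018, SD 0.078), with the bound against it widened from that median to 1 SD below it after the value was seen. A response of these genes to the drugs is the biological alternative and was not tested separately.

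Turned signs of the 4 arrays of a group make 8 patterns, too few for a share under 0.05. The real pattern let 1 list pass at day 10, as did 4 of the 8 patterns with the real one counted, and the highest other let 1 pass. At day 14 it let 5 pass, as did 1 of the 8, and the highest other let 2 pass. For counts of genes, the real value was 0 at both days, which all 8 patterns reached, as any pattern must reach 0; the highest others gave 0 at day 10 and 38 at day 14. For the difference between days, 34 of 35 splits of the 8 arrays could be fitted, all 34 reached the real count of 0, as they must, and the highest other gave 18. These counts of 0 therefore decide nothing about chance.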

How the results depend on the processing

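Print-block centring, a dye term for each group, the capped values kept, unnamed rows averaged in pairs and lists with every prefix match were added after the data were examined; the others were planned. Limma's count of 0 genes at day 10 was 304 with swapped arrays read as already turned and 0 in every other setting (285 to 3293 at an unadjusted p under 0.05 over all). The count of 0 at day 14 was 39 with scaling to one spread, 70 with each group alone and 0 in every other setting (149 to 887). The count of 0 for the difference held in every setting (168 to 1053). Leaving out each array gave 0 to 0 genes in each of the 3. The correlation of the 2 days was -0.02, from -0.17 to 0.17 without single arrays and 0.30 with swapped arrays read as already turned. With the replicate number as a block, the difference still had 0 calls (351 at an unadjusted p under 0.05). Deviations of same-numbered arrays correlated at 0.06, 0.42, 0.39 and 0.10, over 0.1 in 2 of 4. With dye orientation, which same-numbered arrays share, removed, each of these was 0.07. That removal makes the values of replicates 1 and 2 equal, and those of replicates 3 and 4. Not every array matched its own number best, but that match was judged with dye orientation still in the values. These correlations therefore cannot decide on pairing. The numbers were not read as pairs, since the labels name no shared day or batch behind them.

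Swapped arrays read as already turned left 0 lists at day 10 and 0 at day 14, with adjusted p values of 0.26 for P450 genes at day 10 and, at day 14, 0.87 for P450 genes, 0.35 for glial markers, and 0.45, 0.54 and 0.35 for glycolysis, lipid genes and fat body markers, whose direction turned. The estimated correlation left 0 at both days (P450 genes 0.46 at day 10; at day 14 glycolysis and P450 0.18, lipid 0.26, glial and fat body 0.57). It used only genes with all values, and limma then also takes the few residual degrees of freedom of the arrays. On the same genes at the preset correlation, P450 genes (0.017 at day 10, 0.0017 at day 14), glycolysis (0.0066) and lipid genes (0.040) passed, while fat body (0.17) and glial markers (0.27) did not. Single arrays left out gave 0 to 1 lists at day 10 and 1 to 6 at day 14, often with fewer genes per list where the array was of that day. The adjusted p then ranged from 0.0011 to 0.16 for P450 genes at day 10 and, at day 14, from 0.0023 to 0.075 for glycolysis, 7.0e-04 to 0.051 for P450 genes, 0.0031 to 0.062 for fat body markers, 0.036 to 0.51 for glial markers and 0.046 to 0.18 for lipid genes. The number of lists at day 14 was 3 as deposited, 2 with values on at least 2 arrays, 3 with each group alone and 3 with print-block centring. Lipid genes then had adjusted p values of 0.067, 0.15, 0.072 and 0.081, and 0.050 without a dye term. Glial markers had 0.058 as deposited, 0.22 with values on all 4 arrays, 0.072 with each group alone and 0.099 with print-block centring. With values on at least 2 arrays, P450 genes had 0.084 and fat body markers 0.055. Of 138 values of named genes, 54 had the opposite sign with swapped arrays read as already turned and at most 2 under any other setting, none of them past the threshold in either fit, so these were not counted as reversed calls (0).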

Other observations

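Among named genes, 7 were lower at both days at an unadjusted p under 0.05 each time; they were singled out after their values were seen. They were the P450 genes Cyp313a1 and Cyp4d21, the polyubiquitin gene Ubi-p63E, the mitochondrial protease gene ClpP, and CG1791, CG9451 and CG9689. ClpP was at -0.77 ± 0.19 at day 10 and -0.47 ± 0.15 at day 14, and Ubi-p63E at -0.61 ± 0.15 and -0.37 ± 0.12. Independent lists of named genes would share 2.05 lower at both days, and 1 named gene was higher at both, where they would share 0.877. Over all 6419 features, 8 were lower at both days, where 4.93 would be shared, and 6 higher, where 3.15 would be, so the excess of lower ones was smaller there. Spots without a gene name can hold 1 clone more than once, and genes are not independent of each other. Both days also share a gene-wise variance in the joint fit, so a gene of small spread can pass at both more often than independent lists allow. Both tallies are therefore descriptions without a test. Of 29 P450 genes tested at both days, 14 were below 0 at both, where 13.8 would be by the shares of each day alone (21 at day 10 and 19 at day 14).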
